A study of Mus musculus with 11 samples.

How the data were processed

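Gene expression was measured by RNA sequencing of hearts from female C57BL/6NTac mice, an inbred laboratory strain. Per the labels' protocols, mice were 8 weeks old when they were put on a control diet, with 10.4% of its energy from fat, or on an obesogenic diet for 24 weeks. The obesogenic diet combined a solid diet with 60.3% of its energy from fat with sweetened condensed milk. From week 16, some obese mice received dasatinib at 5 mg/kg and quercetin at 50 mg/kg by gavage in 10% PEG400, and the other obese mice received the PEG400 vehicle. Dasatinib is a tyrosine kinase inhibitor and quercetin a plant flavonoid, and the pair is used as a senolytic cocktail, meant to remove senescent cells. Whether control-diet mice were gavaged is not given in the sources used here. The labels placed 4 libraries on the control diet, 4 in the obese group and 3 in the obese group given the cocktail.

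The deposited table held whole numbers per Ensembl mouse gene identifier for the 11 libraries, analysed here as read counts. Whether they are counted reads or estimates from coverage is not given in the sources used here. The submitters' processing notes name cutadapt, HISAT2 and StringTie, without versions, and the genome build GRCm38. The gene annotation, the counting settings and the use of strand are not given in the sources used here. Of 55487 identifiers, 55227 were found in a GENCODE annotation of GRCm38, which supplied symbols, positions and gene types, and 260 had no name there. A symbol carried by more than 1 identifier, which applied to 113 symbols, was taken from the identifier with the largest total. Without a stated use of strand, reads of a gene and of an antisense partner cannot be separated. Genes with near-identical copies are uncertain for the same kind of reason, among them Acot1 and Acot2, the Scd, Nat8 and globin families, Hspa1a and Hspa1b, immunoglobulin genes, and mitochondrial genes with nuclear copies.

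Library totals ran from 52.74 to 103.29 M counts. Genes were filtered with edgeR's filterByExpr, whose minimum count was 10 and minimum total 15, which left 23779 genes. Library sizes were scaled by TMM, and all 11 libraries were fitted in 1 model of 3 groups with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit with robust estimation, glmQLFTest). The comparisons were obese against control diet, cocktail-treated obese against obese, and cocktail-treated obese against control diet. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The common biological coefficient of variation was 0.259. A standard error was the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM values computed from the deposited counts with TMM-scaled library sizes, given as mean ± SD over libraries. The log2 CPM values used a prior count of 1.

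A total of 40 gene lists, with 871 distinct symbols, were fixed before the data were examined, and 31 symbols stood in more than 1 list. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 40 lists. Camera with an estimated correlation and fry (limma 3.58.1) were run beside it. With an estimated correlation, 0 lists passed in any of the 3 comparisons. Fry asks whether a list's genes move on balance in 1 direction and does not compare the list with other genes.

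Named genes followed a rule fixed at the same time. Among genes with a symbol other than a predicted-gene name, a mean of at least 1 CPM, an adjusted p under 0.05 and groups that did not overlap in log2 CPM, the 6 largest rises, the 6 largest falls and the next 6 smallest p were taken. From each list that camera called, or that held at least 2 called genes, the 4 members with the smallest p were added. Where fewer than 6 genes passed, the 6 smallest p were given as values. Cdkn1a, Cdkn2a, Gdf15, Nppa, Nppb, Myh7, Col1a1 and Pdk4 were always given in the comparisons of diet and of cocktail. Some genes that these rules take are not reported here. Library measures were compared with 2-sided exact permutation tests, 51 in all, for which 0.0286 was the smallest p possible.

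The labels do not say that each library came from a separate animal, so p-values measure the spread between libraries, which may be technical in part. Libraries of 1 group differed from each other by far more than sampling noise, and none was treated as a repeat. Alternatives set beforehand were other scalings, other low-count filters, fits of only the groups compared, a replicate block, 1 surrogate variable (sva 3.50.0), DESeq2 1.42.0, limma voom with and without quality weights, other list tests, leaving out each library, and a split of the obese libraries. Alternatives added after the data were seen were an atrial marker score or the intronic share as a covariate, leaving out the 3 libraries with the highest atrial score (obese replicate 3 and treated replicates 2 and 3), thinning to equal depth, removing GC and length trends, and restricting or removing gene classes.

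The procedure was tested on simulated counts of 23779 genes, of which 200 were changed. In the diet comparison it recovered 9% of genes changed 1.5-fold, 37.3% of those changed 2-fold and 81.8% of those changed 4-fold. The corresponding shares were 7.5%, 38.8% and 81.8% for the cocktail comparison, and 4.5%, 38.8% and 78.8% for treated obese against control diet. False calls made up 6.6%, 9.5% and 3.6% of calls, in that order. A list shifted 1.5-fold in each simulation ranked 1 among the lists, and 0 other lists passed. Simulated genes varied independently of each other, unlike members of the real lists. The estimated correlation was 0.914 for respiratory chain subunits in the diet comparison. The simulation therefore does not measure false calls of lists in these data. It also changed 200 genes, whereas 7166 passed for the diet and 3760 for treated obese against control diet. Benjamini-Hochberg adjustment is stricter when fewer genes change. The recovered shares therefore do not give the sensitivity of either of those comparisons.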

Results

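RNA was sequenced from hearts of 4 control-diet, 4 obese and 3 cocktail-treated obese libraries. Library totals were 88.6 ± 12.4 M counts on the control diet (SD, n = 4), 57.1 ± 6.84 M in obese libraries (SD, n = 4) and 68.3 ± 4.04 M in treated libraries (SD, n = 3). Every control library was deeper than every obese and treated library. Genes of the mitochondrial chromosome took 29.9% ± 1.92 of counts on the control diet (SD, n = 4), 23.0% ± 1.28 in obese libraries (SD, n = 4) and 20.2% ± 2.28 in treated libraries (SD, n = 3). Genes of the annotation classes sense-intronic and TEC (loci that still await experimental evidence), together called the intronic share here, took 0.399% ± 0.139, 0.732% ± 0.0629 and 0.603% ± 0.0842 in the same order. For the intronic share, the exact permutation p of obese against control diet was 0.0286, the smallest possible, with an adjusted value of 0.0858 over 51 tests.

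The comparison of obese with control-diet hearts asks how cardiac gene expression differed with the obesogenic diet. Obese mice also received the PEG400 vehicle by gavage, and whether control-diet mice did is not given. Effects of diet and of gavage therefore cannot be told apart, and changes with the diet below are differences between these groups. Many genes of fatty acid use fell. Pdk4, a kinase that restrains pyruvate oxidation, went from 2496 ± 289.7 CPM on the control diet to 300 ± 129.6 CPM in obese hearts, 8.32-fold lower (log2 fold change -3.06, SE 0.30, edgeR adjusted p = 7.97e-05). Angptl4, an inhibitor of lipoprotein lipase, was 7.75-fold lower (adjusted p = 0.000765). Scd4, a stearoyl-CoA desaturase, had the largest fall by the rule, 18.2-fold, from 140.7 ± 36.5 to 7.73 ± 2.74 CPM (adjusted p = 6.24e-05). It stands in the list of fatty acid and triglyceride synthesis. That list did not pass, with 1 of 21 genes risen and 6 fallen, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.151). In Pdk4, Angptl4 and Scd4 all 4 obese libraries lay below all 4 control libraries, as the naming rule required. In GRCm38, Pdk4 lies on chromosome 6 from 5483351 to 5496309, and Scd4 on chromosome 19 from 44333092 to 44346743.

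Of 26 PPAR-alpha target genes tested, 20 fell and 0 rose, with a median log2 fold change of -1.25 (camera adjusted p = 3.54e-25; adjusted p = 0.0664 with an estimated correlation). The same 20 falls passed when adjusted over the list alone. Acot1 and Acot2, acyl-CoA thioesterases with similar sequences, were 6.57-fold and 4.56-fold lower. Of 23 mitochondrial beta-oxidation enzymes, 19 fell and 1 rose (median -0.89, adjusted p = 2.33e-13; adjusted p = 0.562 with an estimated correlation), and 20 fell and 1 rose adjusted over the list alone. Acadl, a long-chain acyl-CoA dehydrogenase, fell 2.05-fold and Eci1 2.21-fold. Of 51 nuclear-encoded respiratory chain subunits, 46 fell and 0 rose (median -0.74, adjusted p = 2.86e-18; adjusted p = 0.562 with an estimated correlation), among them Uqcrb, 2.31-fold, and Ndufa9, 1.91-fold. All 13 mitochondrially encoded messenger RNAs fell (median -0.80, adjusted p = 3.49e-09; adjusted p = 0.562 with an estimated correlation). For example, mt-Nd5 was 2.06-fold lower. The share of the mitochondrial chromosome and the intronic share, given above, moved with these lists.

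**Figure D1:**
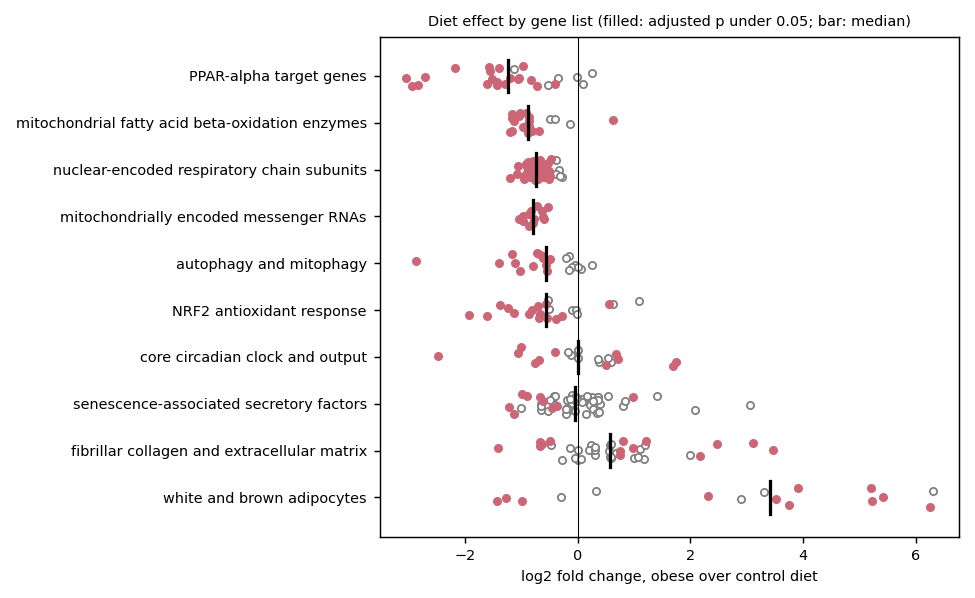
Log2 fold change of obese over control-diet hearts for each tested member of 10 gene lists; filled points have an adjusted p under 0.05 and the bar is the list's median. The PPAR-alpha list has its median at -1.25, and the adipocyte list spreads over both sides of 0.

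The autophagy, NRF2, glucocorticoid and insulin signalling lists were called down as well. Of 21 autophagy and mitophagy genes, 13 fell and 0 rose (median -0.58, adjusted p = 5.85e-10; adjusted p = 0.502 with an estimated correlation). Bnip3, a mitophagy receptor, fell 7.33-fold, from 436.3 ± 76.0 to 59.6 ± 13.9 CPM (adjusted p = 5.47e-06), Map1lc3b fell 2.64-fold and Sqstm1 2.27-fold. Of 22 NRF2 target genes, 14 fell and 1 rose (median -0.56, adjusted p = 8.96e-08; adjusted p = 0.502 with an estimated correlation). Adjusted over the list alone, 1 autophagy gene rose and 13 fell, and 2 NRF2 targets rose and 14 fell. Gclm, a subunit of the first enzyme of glutathione synthesis, fell 3.83-fold and had the smallest adjusted p of the comparison, 3.35e-06. Catalase (Cat) fell 3.06-fold. Of 17 glucocorticoid-responsive genes, 8 fell and 0 rose (median -0.49, adjusted p = 0.000155; adjusted p = 0.562 with an estimated correlation). Pdk4 and Angptl4 stand in that list as well, and the metallothionein gene Mt1 fell 2.43-fold. Of 18 insulin signalling genes, 7 fell and 0 rose (median -0.30, adjusted p = 0.00849; adjusted p = 0.562 with an estimated correlation), including the insulin receptor gene Insr, 2.01-fold lower. The unfolded protein and integrated stress response, with 2 of 24 genes risen and 9 fallen, did not pass (camera adjusted p = 0.0801). Neither did the cytosolic heat shock response, with 4 of 18 risen and 8 fallen, or 6 and 10 adjusted over the list alone (camera adjusted p = 0.158).

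Of 25 sarcomere and calcium-handling genes, 8 fell and 0 rose (median -0.35, adjusted p = 0.00164; adjusted p = 0.741 with an estimated correlation), among them Actn2, 1.81-fold lower, and phospholamban (Pln), 1.96-fold lower. Myh7, the slow myosin heavy chain, was 1399 ± 427.9 CPM on the control diet and 916.3 ± 152.7 CPM in obese hearts (adjusted p = 0.0396). Its call was lost without control replicate 1 or 4, obese replicate 1, 3 or 4, or treated replicate 3 (adjusted p from 0.0501 to 0.136). Nppb, which encodes B-type natriuretic peptide, was 66.0 ± 63.2 CPM on the control diet and ran from 4.02 to 19.9 CPM in obese libraries, with groups that overlapped (log2 fold change -2.58, adjusted p = 0.0467). Control replicate 4 held 158.0 CPM, and without it the log2 fold change was -1.69 (adjusted p = 0.12). The call of Nppb was also lost without control replicate 1, any of the obese replicates, or treated replicate 2 or 3 (adjusted p from 0.0544 to 0.1). Nppa was 35.4 ± 13.6 CPM on the control diet and 213.7 ± 333.3 CPM in obese hearts and did not pass (adjusted p = 0.196). Of 19 T, NK and B lymphocyte genes, 4 fell and 0 rose (median -0.84, adjusted p = 0.000935; adjusted p = 0.562 with an estimated correlation). Igkc, an immunoglobulin light chain constant region, fell 5.31-fold, and Igha, an antibody heavy chain gene named by the rule on size, 8.98-fold. Several lymphocyte genes were near or below 1 CPM.

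The core circadian clock changed in both directions. Of 19 clock genes, 5 rose and 6 fell, and the list as a whole did not pass (camera adjusted p = 0.86). Arntl, which encodes the activator BMAL1, fell 5.62-fold, from 14.3 ± 5.91 to 2.54 ± 0.411 CPM (adjusted p = 0.000259), and Clock fell 1.69-fold. Per2 and Per3, which encode repressors of the clock, rose 3.34-fold and 3.24-fold (adjusted p = 0.000368 and 0.000107). Collection times are not given in the sources used here.

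The senescence lists did not pass camera. Cdkn1a, which encodes the cell cycle inhibitor p21, fell 3.25-fold, from 43.0 ± 4.82 to 13.2 ± 2.18 CPM (adjusted p = 0.00023). Cdkn2a held 60 counts over all 11 libraries and was not tested. Among 30 senescence markers and anti-apoptotic genes, 2 rose and 6 fell (camera adjusted p = 0.0801). Among 50 senescence-associated secretory factors, 1 rose and 8 fell (camera adjusted p = 0.276), with Vegfa 1.96-fold higher and Mmp14, a membrane metalloproteinase gene, lower by a log2 fold change of -0.91. The median of the secretory list was -0.05 and 0.05 under upper-quartile scaling. Among 28 p53 targets, 1 rose and 5 fell (camera adjusted p = 0.235), and the median, -0.08, was 0.03 under upper-quartile scaling. Adjusted over the list alone, 1 secretory factor rose and 5 fell, and 1 p53 target rose and 4 fell. The secretory list had a mean of 0.01, opposite in sign to its median and its test. Fry, which does not compare a list with other genes, called the senescence markers down (fry adjusted p = 0.0243). It did not call the secretory factors or the p53 targets (fry adjusted p = 0.578 and 0.102).

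Camera called 0 lists up with the diet. Among 40 fibrillar collagen and matrix genes, 9 rose and 5 fell (camera adjusted p = 0.158). Col15a1 rose 2.32-fold and Col5a1 1.67-fold, while the collagen cross-linking enzyme gene Lox fell 2.69-fold. Col1a1 was 50.7 ± 13.5 CPM on the control diet and 76.2 ± 34.0 CPM in obese hearts (adjusted p = 0.201). Of the matrix genes, 10 rose and 5 fell adjusted over the list alone. Among 16 adipocyte genes, 8 rose and 3 fell (camera adjusted p = 0.466), and 11 rose and 3 fell adjusted over the list alone. Adipoq, an adipocyte hormone gene, went from 0.0156 ± 0.0312 to 0.669 ± 0.600 CPM, while Fabp4, also expressed by other heart cells, fell 2.42-fold. The mean log2 CPM of the adipocyte list was -1.44 on the control diet and 0.37 in obese hearts (exact permutation p = 0.0286, adjusted value 0.0858). Tfrc, the transferrin receptor gene, rose 3.58-fold, from 15.5 ± 0.955 to 55.5 ± 8.50 CPM (adjusted p = 1.08e-05). The largest rises by the rule were in Nat8f3, Cntn2, Unc80, Prnd, Sfrp5 and Comp. Cntn2, a neural cell adhesion gene also used as a marker of the conduction system, went from 1.70 ± 1.28 to 40.8 ± 37.5 CPM (adjusted p = 0.0168). It was 91.8 CPM in obese replicate 3, the obese library with the highest atrial score, against 3.34 to 42.2 CPM in the other obese libraries. Without that replicate, the log2 fold change of Cntn2 went from 4.57 to 3.80, and Nat8f3, Sfrp5 and Comp were 3.53, 2.48 and 3.13 and did not pass (adjusted p = 0.0532, 0.0649 and 0.0607). Nat8f3 and Sfrp5 also did not pass without any 1 of the control replicates, Comp without control replicate 1, 2 or 4 or obese replicate 2, and Prnd without obese replicate 2 (adjusted p from 0.0602 to 0.0858).

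In all, 7166 of 23779 genes changed with the diet by edgeR's quasi-likelihood test, 3429 up and 3737 down, of which 1560 rose and 535 fell at least 2-fold. Upper-quartile scaling raised the median of all genes by 0.102 and gave 4378 up and 2926 down. No other scaling moved that median by over 0.1 (log2), and none turned the median of a list called in this comparison. Groups did not overlap for 28.5% of genes, against 2.86% by chance. Camera called 10 lists, all down. Under settings chosen after the data were seen, the calls were 4 up and 7 down with the intronic share as a covariate and 1 up and 7 down with protein-coding genes only. For the lists above with no other count given, the count adjusted over the list alone was the same. With the intronic share as a covariate 120 genes passed, and Pln and Myh7 had log2 fold changes of 0.10 and 0.12. Nppa was -1.03 with an atrial marker score as a covariate.

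**Figure D2:**
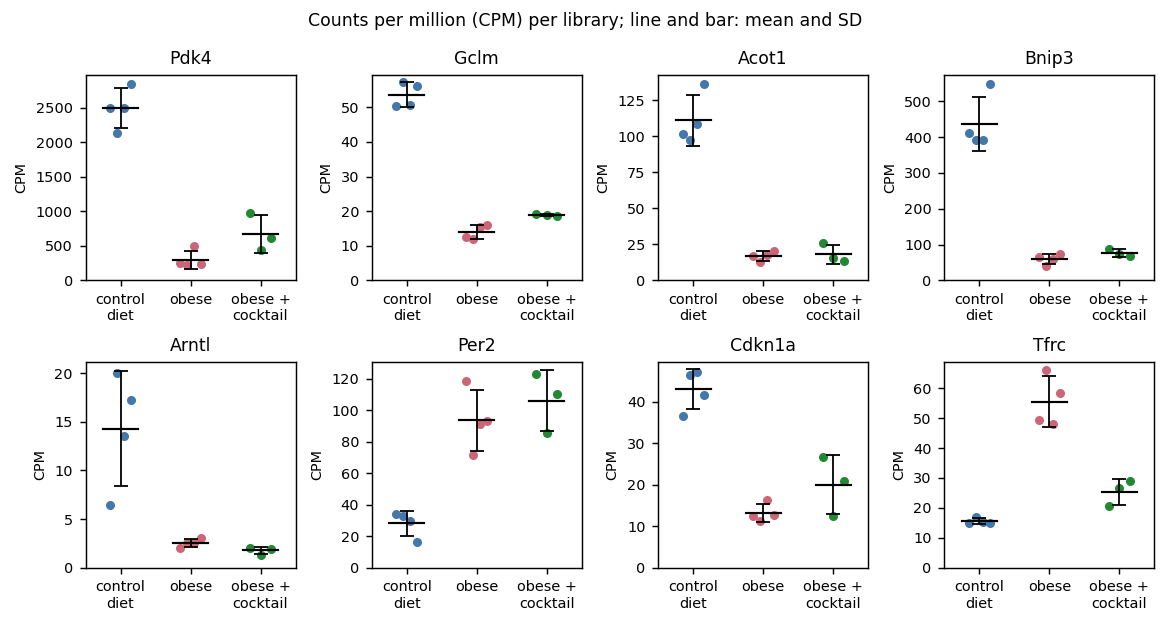
CPM of 8 genes in each library by group; points are libraries, horizontal lines are means and bars are SD. Pdk4 averaged 2496 CPM on the control diet, 300 CPM in obese and 674.4 CPM in treated libraries.

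The comparison of cocktail-treated with untreated obese hearts asks what the cocktail, meant to remove senescent cells, did to cardiac gene expression in obese mice. No gene passed edgeR's quasi-likelihood test. The smallest adjusted p belonged to Tfrc, at 55.5 ± 8.50 CPM in obese hearts and 25.5 ± 4.36 CPM in treated hearts (log2 fold change -1.13, SE 0.14, adjusted p = 0.0518). Fstl4 followed, at 6.84 ± 1.05 and 15.0 ± 0.774 CPM (adjusted p = 0.0664), then Doc2g, Kcnc1, Lilrb4a and Gabarapl1 with adjusted p from 0.124 to 0.184. Pdk4 was 300 ± 129.6 CPM in obese and 674.4 ± 277.9 CPM in treated hearts (log2 fold change 1.17, SE 0.30, adjusted p = 0.354), Cdkn1a had a log2 fold change of 0.60 (adjusted p = 0.407), and Gdf15 was 1.14 ± 0.722 and 1.66 ± 0.588 CPM (adjusted p = 0.67). Nppa, Nppb, Myh7 and Col1a1 had log2 fold changes of 2.45, 0.94, 0.59 and -0.15, with adjusted p of 0.584, 0.724, 0.418 and 0.905. The unadjusted p was under 0.05 for 2425 genes, against 1189 by chance. Limma voom called 1 gene and DESeq2 131, 51 up and 80 down. The DESeq2 calls included Tfrc, Fstl4, Doc2g, Kcnc1, Lilrb4a, Gabarapl1 and Pdk4 (DESeq2 adjusted p from 2.64e-08 to 0.024), so their calls depend on the method. They also included the predicted genes Gm20431 and Gm49333, with implausibly large log2 fold changes of 22.8 and -21.9. Without obese replicate 3, 24 genes passed. Col1a1 was 0.21 without obese replicate 2 and 0.14 without treated replicate 1 (log2 fold change).

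At the level of lists, camera called 16 lists up and 3 down, and with an estimated correlation none passed, the smallest adjusted p being 0.476. With the intronic share as a covariate, chosen after the data were seen, the calls were 7 up and 8 down. Proliferation genes were the strongest down list (30 tested, median -0.71, adjusted p = 2.02e-10; adjusted p = 0.476 with an estimated correlation). Top2a was 3.17 ± 1.77 CPM in obese and 0.748 ± 0.0908 CPM in treated hearts, and Mki67 12.1 ± 7.30 and 2.83 ± 0.484 CPM. In this list 10 genes were lower adjusted over the list alone. Erythrocyte genes were down as well (10 tested, median -0.77, adjusted p = 1.7e-08; adjusted p = 0.476 with an estimated correlation), and 6 were lower adjusted over the list alone. Mitochondrially encoded messenger RNAs had a median of -0.15 (adjusted p = 0.0143; adjusted p = 0.91 with an estimated correlation), which became 0.06 once GC and length trends were removed.

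Lists called up included glucocorticoid-responsive genes (median 0.43, adjusted p = 9.95e-07), the unfolded protein and integrated stress response (0.29, 7.04e-06 as adjusted p), autophagy and mitophagy (0.20, adjusted p = 4.82e-05), NRF2 targets (0.26, adjusted p = 0.000113), insulin signalling (0.22, adjusted p = 0.000172) and PPAR-alpha targets (0.22, adjusted p = 0.000518). Each of these 6 had adjusted p = 0.476 with an estimated correlation. Adjusted over the list alone, 5 glucocorticoid-responsive genes, 4 autophagy genes, 4 NRF2 targets, 2 insulin signalling genes, 2 PPAR-alpha targets and 1 gene of the unfolded protein list were higher. Mt1 and Mt2 were 2.35-fold and 3.51-fold higher in treated hearts, each with adjusted p = 0.354 over all genes. Respiratory chain subunits (median 0.15, adjusted p = 0.00049; adjusted p = 0.918 with an estimated correlation), glycolysis (0.17, adjusted p = 0.00159; adjusted p = 0.744 with an estimated correlation), heat shock (0.25, adjusted p = 0.00151; adjusted p = 0.744 with an estimated correlation) and hypertrophy genes (0.24, adjusted p = 0.0121; adjusted p = 0.744 with an estimated correlation) were also called up. So were xenobiotic response genes (0.26, adjusted p = 0.0156; adjusted p = 0.476 with an estimated correlation), in which Cyp1a1 lay below 1 CPM in both groups. Nppa, of the hypertrophy list, also stands in the list of atrial myocyte genes given below. It was 34.3, 1116 and 2346 CPM in treated replicates 1, 2 and 3, and ran from 12.6 to 712.1 CPM in obese libraries. The call of hypertrophy genes thus does not show a hypertrophy response apart from atrial markers.

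Marker lists of other tissues or cell types were called up in the same comparison. These were mesothelial genes (median 2.34, adjusted p = 8.74e-06; adjusted p = 0.476 with an estimated correlation), atrial myocyte genes (1.48, adjusted p = 4.11e-05; adjusted p = 0.605 with an estimated correlation), skeletal muscle genes (0.30, adjusted p = 0.0257; adjusted p = 0.476 with an estimated correlation), fibroblast genes (0.22, adjusted p = 0.0307; adjusted p = 0.91 with an estimated correlation) and neural genes (0.31, adjusted p = 0.0484; adjusted p = 0.91 with an estimated correlation). The atrial score, the mean log2 CPM of 5 atrial genes, was 0.45, 7.13 and 8.93 in the 3 treated libraries and -1.24, 2.51, 7.75 and 4.26 in the 4 obese libraries. Its exact permutation p was 0.514. The mean log2 CPM of the mesothelial list was -1.68, 2.42 and 1.68 in the treated libraries. In the obese libraries it was -2.55, -0.64, 0.47 and -1.27 (exact permutation p = 0.2). Of the 14 skeletal muscle genes, 10 were tested, and the skeletal myosin gene Myh4 had 0 counts over all 11 libraries. Acta1, of the same list, also stands in the hypertrophy list. The call thus does not show skeletal muscle in the samples. Senescence markers (30 tested, camera adjusted p = 0.854) and secretory factors (50 tested, camera adjusted p = 0.271) did not pass. The senescence list had a median of 0.02 and a mean of -0.01, with 0 members passing over all genes or adjusted over the list alone.

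**Figure D3:**
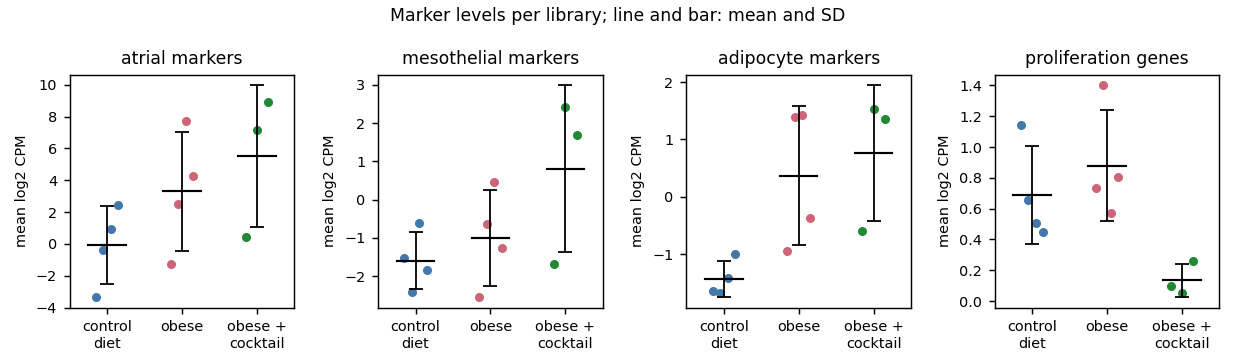
Mean log2 CPM of atrial, mesothelial, adipocyte and proliferation genes in each library by group; points are libraries, lines are means and bars are SD. Proliferation genes ran from 0.05 to 0.26 in the 3 treated libraries, below the 4 obese libraries.

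The comparison of treated obese with control-diet hearts asks how far treated hearts differed from hearts of the control diet. PPAR-alpha targets were again lower, with 19 of 26 fallen and 0 risen (median -0.95, camera adjusted p = 1.92e-21; adjusted p = 0.0724 with an estimated correlation). Cd36, a fatty acid transporter gene, went from 2357 ± 301.1 to 772.8 ± 128.1 CPM, and Acot1 fell 6.11-fold. Beta-oxidation enzymes (18 of 23 fallen, median -0.85, adjusted p = 1.41e-13; adjusted p = 0.415 with an estimated correlation), respiratory chain subunits (21 of 51 fallen, median -0.61, adjusted p = 1.95e-14; adjusted p = 0.584 with an estimated correlation) and all 13 mitochondrially encoded messenger RNAs (median -0.94, adjusted p = 1.95e-16; adjusted p = 0.415 with an estimated correlation) were lower too. Autophagy genes (7 fallen, 1 risen, adjusted p = 8.9e-06) and NRF2 targets (8 fallen, 3 risen, adjusted p = 0.000395) were lower, each with adjusted p = 0.415 with an estimated correlation. Adjusted over the list alone, 20 PPAR-alpha targets, 19 beta-oxidation enzymes, 39 respiratory subunits, 9 autophagy genes and 10 NRF2 targets fell, and 1 beta-oxidation enzyme, 1 autophagy gene and 3 NRF2 targets rose. Bnip3 fell 5.72-fold and Gclm 2.83-fold. Arntl fell 8.09-fold and Per2 rose 3.78-fold.

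Mesothelial genes (6 of 12 risen, adjusted p = 0.000488; adjusted p = 0.584 with an estimated correlation), atrial genes (1 of 13 risen, adjusted p = 0.000359; adjusted p = 0.701 with an estimated correlation) and neural genes (2 of 13 risen, adjusted p = 0.0348; adjusted p = 0.749 with an estimated correlation) were the lists called up. Among the lists called down, lymphocyte genes had 4 of 19 fallen (adjusted p = 2.13e-06; adjusted p = 0.415 with an estimated correlation) and proliferation genes 7 of 30, with 1 risen (adjusted p = 0.00396; adjusted p = 0.712 with an estimated correlation). Senescence markers (7 fallen and 1 risen of 30, adjusted p = 0.0256), neutrophil and mast cell genes (2 fallen of 10, adjusted p = 0.0182) and smooth muscle genes (5 fallen of 16, adjusted p = 0.0196) each had adjusted p = 0.415 with an estimated correlation. Sarcomere genes (4 fallen of 25, adjusted p = 0.00396; adjusted p = 0.749 with an estimated correlation) and erythrocyte genes (2 fallen of 10, adjusted p = 0.019; adjusted p = 0.721 with an estimated correlation) completed the lists called down. Adjusted over the list alone, 10 mesothelial and 11 atrial genes rose and 12 lymphocyte, 9 proliferation, 8 senescence, 6 sarcomere, 6 smooth muscle and 3 erythrocyte genes fell, while 2 proliferation genes and 1 senescence marker rose. The largest rises by the rule, Nat8f3, Cilp2, Mlana, Lmntd1, Tmem163 and Cpne5, had SDs close to their means in treated hearts. Cilp2, for example, was 20.3 ± 17.6 CPM. The calls of all 6 were lost without control replicate 1, 3 or 4 or treated replicate 3 (adjusted p from 0.0541 to 0.128). Those of all but Mlana were lost without control or treated replicate 2 (adjusted p from 0.0585 to 0.0798), those of Lmntd1 and Cpne5 without obese replicate 2 or 4, and that of Cilp2 without obese replicate 4. In all, 3760 genes changed, 1766 up and 1994 down, and camera called 16 lists, 3 up and 13 down. Without treated replicate 3 the count was 1011, and it was 1857, 2473 and 1816 without control replicates 1, 3 and 4. With the intronic share as a covariate it was 508, with 9 lists up and 11 down.

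Both comparisons against the control diet called 1337 genes up and 1698 down, where independent lists would share 254.7 and 313.4, and 0 genes were called in opposite directions. They share the control libraries, which adds overlap with no effect: the covariance of their log2 fold changes was 0.522, against 0.0770 in 20 simulations of unchanged groups. The diet and cocktail effects share the obese libraries with opposite sign. Their covariance across genes was -0.1047 (Pearson r -0.28 across genes, which are not independent replicates), against -0.0772 in those simulations, a difference of -0.0275, and the observed covariance had a jackknife SE over libraries of 0.0779. The simulated r was -0.46. The simulations held no diet effect, whose spread enters the denominator of r, so the simulated and observed r cannot be compared. With each comparison given a separate pair of the obese libraries, the mean covariance was -0.0148, from -0.0779 to 0.0906 over the 6 divisions. In those divisions 71.9% of the genes called for diet, from 61.5% to 81%, had a cocktail effect of the opposite sign, and 50.2% of all genes had a negative one. Genes are not independent, and this share was not tested.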

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

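Values of each library were compared within the control and obese groups, and a value was singled out when its gap to the nearest of the others was large against the group's range. Of 112 groups of values, 8 were singled out, where chance gives about 5.6, and 7 of the 8 are given here. Obese replicate 4 had 67.25 M counts, against 52.74 to 54.97 M in the other obese libraries. Obese replicate 2 had counts in 32106 genes, against 31049 to 31213. Control replicate 4 had a mean log2 CPM of erythrocyte genes of 3.21, against 3.87 to 3.99, and a Bnip3 log2 CPM of 9.10, against 8.62 to 8.68. Control replicate 3 had an Unc80 log2 CPM of -1.71, against -2.14 to -2.10. Obese replicate 3 had a Scd4 log2 CPM of 3.56, against 2.62 to 2.76, and a Pdk4 log2 CPM of 8.95, against 7.81 to 7.98. For the 4 genes named here, the value singled out stayed on its own group's side of the other group, as the naming rule required.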

How the results depend on the processing

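Of 145 genes named in the diet comparison, 138 were past the threshold, and 15 of them were past it in the same direction in every setting. For treated against control these were 141 and 27 of 158. Every setting includes the intronic share as a covariate, under which few diet calls remained. It also includes the fit without the 3 libraries richest in atrial markers, so the 27 depends in part on a fit with 1 treated library. The cocktail comparison gave 0 genes in the reported fit, 2 with upper-quartile normalization, 2 with no low-count filter, 131 with DESeq2, 1 with limma voom and 3 with voom quality weights. Leaving out the 3 libraries richest in atrial markers keeps 1 treated library, so the values of that setting for both comparisons with treated hearts rest on 1 sample and carry no weight here. It gave 5 genes for the cocktail and 378 for treated against control. The cocktail comparison gave 1 at equal depth and 2 with protein-coding genes only. Treated obese against control diet gave 6179 genes with voom quality weights and 508 with the intronic share as a covariate. The diet count was 120 with that covariate, which correlated with diet group at 0.872 over 8 libraries. The median SE of the 7166 calls rose from 0.167 to 0.271 and their median absolute log2 fold change went from 0.753 to 0.394, with 90.4% keeping their sign. With an estimated correlation 0 lists passed in each comparison, and fry called 14 down for diet, 0 for the cocktail and 11 down for treated against control. List directions for the cocktail, 16 up and 3 down, were 7 and 8 with the intronic share and 9 and 6 without the atrial-rich libraries. Other causes were not tested.

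The covariance of the diet and cocktail effects, -0.1047, was -0.7945 with no low-count filter, -0.0148 with separate obese libraries in each comparison, -0.2794 without the 3 atrial-rich libraries (1 treated library) and -0.2094 with the intronic share. Leaving out each library gave 4917 to 8153 genes for diet, 0 to 24 for the cocktail and 1011 to 4652 for treated against control. It gave 10 to 14, 14 to 19 and 13 to 20 lists in the same order, and a covariance from -0.1647 to -0.0923.

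Some named genes changed sign (log2 fold change). In treated against control, Mbp was -0.072 with 1 surrogate variable, -0.022 with the atrial score and -0.46 without the atrial-rich libraries (1 treated library), where Myl4 was -0.006. For the cocktail, Col1a1 was 0.091 with quality weights. Leaving out each library took it from -0.337 without treated replicate 2 to 0.206 without obese replicate 2, and it was 0.137 without treated replicate 1. With 1 treated library left, without the atrial-rich libraries, Ankrd1 was -0.10, Krt7 -0.23, Gja5 -0.48, Mbp -0.11, Gdf15 -0.22, Nppa -0.47 and Nppb -0.77. Cox6a2 was -0.024 with the intronic share. For diet, Nppa was -1.03 with the atrial score. With the intronic share, Slc16a1 was 0.06, Hmgcs1 0.22, Gata4 0.081, Pln 0.10, H2-Ab1 0.14, Prnp 0.016, Pcna 0.026 and Myh7 0.12. The cause was not tested.

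Groups share replicate numbers. Of 10 same-numbered pairs, 3 correlated over 0.1 (range -0.232 to 0.399), with a median of 0.057 against -0.029 for different numbers. The highest values between groups were same-numbered, 0.399 for obese and treated replicates 1 and 0.336 for obese and treated replicates 3. For 6 of 11 libraries the best match carried their own number. The numbers were not taken to pair libraries, but these values do not exclude pairing. A replicate block gave 7112, 0 and 2690 genes, 12, 17 and 17 lists and a covariance of -0.1313.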

Other observations

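The tests of depth, of GC content and length, of the intronic share, of the time of day and of both explanations for the atrial markers were chosen after the results were seen. In the diet comparison, most called genes of the noncoding classes rose. Of 1850 TEC genes, 28.3% rose and 0.6% fell in obese hearts, and of 1578 antisense genes 19.3% rose and 2.2% fell. Of 15644 protein-coding genes, 12.2% rose and 22.2% fell, but a fit of protein-coding genes only, which sets the scaling on them alone, gave 2714 up and 2873 down.

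Ion channel, vascular and hypoxia genes changed in both directions with the diet. Among 27 ion channel genes, 4 rose and 5 fell (camera adjusted p = 0.49; median -0.03 and mean 0.16 differ in sign), with the T-type calcium channel gene Cacna1g 3.46-fold higher and the potassium channel gene Kcnj2 1.79-fold lower. Among 21 endothelial genes 2 rose and 5 fell (camera adjusted p = 0.192), and Cldn5, a tight junction gene, was 2.71-fold lower. Among 20 hypoxia and angiogenic genes, 6 rose and 8 fell (camera adjusted p = 0.49). Dbh, the enzyme of noradrenaline synthesis, was 6.05-fold higher. Among 20 macrophage genes 0 rose and 1 fell (camera adjusted p = 0.49). Adjusted over the list alone, 0 macrophage genes passed and the other counts were the same.

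Against 5 technical explanations, the median of the PPAR-alpha list with the diet, -1.25 (SE over members 0.177), was -1.24 with all libraries thinned to 1 depth and -1.34 with GC and length trends removed. It was -1.07 without the atrial-rich libraries, of which this comparison holds 1, obese replicate 3, and -1.04 with the intronic share as a covariate. None of these settings removed the fall, though leaving out obese replicate 3 does not take out all atrial markers. Of 10000 random protein-coding lists matched on expression, 0 had a median as low, the lowest being -0.675. Random members were drawn independently, whereas the estimated correlation of the PPAR-alpha list was 0.227. Medians of correlated lists spread more, so 0 of 10000 overstates how rare such a median is. Camera with that correlation gave adjusted p = 0.0664. The random medians centred on -0.279, against -0.04 for all protein-coding genes, so the average fall of genes of that expression does not account for the whole. A lower activity of PPAR-alpha in obese hearts may underlie the pattern, a hypothesis that PPAR-alpha binding at these genes, measured in hearts collected at 1 feeding state, would test.

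The clock genes may differ because hearts of the diet groups were collected at different times of day. Of 9 called clock genes assigned to a phase, 8 moved with their phase, Nr1d1 being the exception. Diet and collection time cannot be told apart, since no time is given, and hearts collected at known times would be needed. All 11 called clock genes stayed called in the same direction without the atrial-rich libraries, so the changes do not rest on obese replicate 3. Obese replicates 2 and 4 stayed in, with atrial scores of 2.51 and 4.26 against a control mean of -0.09. Atrial tissue is therefore not excluded. With the intronic share as a covariate 11 kept their direction but 2 were still called, and this explanation stays open.

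The atrial score was above the obese median of 3.38 in 2 of the 3 treated libraries. The other, at 0.45, lay within the obese spread (SD 3.74), so a rise in every treated heart cannot be told apart from a rise in some. Over 7 libraries with both genes above 1 CPM, the SD of log2 Sln to Myl7 was 0.311, while log2 Myl7 itself had an SD of 3.29. Atrial tissue carried along in dissection is a candidate explanation. A larger share of atrial tissue in some obese hearts for biological reasons was not tested.

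Fewer red blood cells and their precursors could account for part of the lower proliferation genes in treated hearts. With the erythrocyte score as a covariate the list's median went from -0.71 to -0.45 (SE over members 0.102), which leaves the question open.

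Other splits of the same libraries were fitted, 35 for each comparison. For the diet, 1 of 35 splits, the real one, gave as many as 7166 genes, the highest other giving 3. For treated against control, 1 of 35 gave as many as 3760, the highest other giving 2139. That other split set control replicate 2 with the 3 treated libraries. A share of 1 of 35 is the smallest these tests can give, and both comparisons use the control libraries. Chance is thus unlikely for these counts of genes but not excluded. For the cocktail, all 35 gave at least the real count of 0, as any split must, so this carries no information. The highest other gave 1096. That split set the 3 atrial-rich libraries apart, which points to a structure of the samples. At an unadjusted p under 0.05, 5 of 35 gave as many as 2425 genes, the highest other giving 4507, so chance is not excluded. For lists, 31 of 35 splits gave as many as the 10 of the diet (highest other 23), 12 of 35 as many as the 19 of the cocktail (highest other 21), and 19 of 35 as many as the 16 of treated against control (highest other 24), so chance is not excluded for any count of lists.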
